A study of Homo sapiens with 36 samples.

How the data were processed

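RNA sequencing of 36 libraries was studied, in 12 groups of 3. In each of 2 cell lines, 293T and MDA-MB-231, a control siRNA (siControl) was set against siEglN2-1 and siEglN2-2, and a control shRNA (shControl) against shKDM5A-1 and shKDM5A-2. Per the labels' protocols, cells grew in DMEM with 10% FBS and 1% penicillin and streptomycin, RNA was taken with Qiagen RNeasy, and libraries were made with an NEBNext Ultra II kit from 1 µg of total RNA. The labels record no date or batch, nor whether the 3 libraries of a group came from separate cultures. The siRNA and shRNA sequences are not given.

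The authors' tables, 1 per experiment, hold 9 columns of raw values and 9 of normalized values. The raw values are counts per the file headers, and the deposited numbers are read here as fractional expected counts, since only 49.3% to 50.4% of them, by table, are whole (remainder of exactly 0, zeros included). The normalized values are on a log2 scale as deposited, but the transformation is not stated, so they were not used here. STAR 2.4.2, Salmon 0.1.19 and the builds GRCh38 and hg19 are named in the submitters' processing notes, without saying which table each made. Coordinates of genes are given for GRCh38. The 3' UTRs come from GENCODE 29, with the longest 3' UTR taken per gene. In each table the lowest of the row maxima was 10, so genes with fewer counts in every library had been taken out before deposition.

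In 293T, 1 raw control column of the siRNA experiment carries no replicate number. It was taken as the remaining siControl library, and is called the unnumbered control. Gene names turned into dates by a spreadsheet were left out (20 to 22 per table), which held 0.194% to 0.209% of counts. This left 18770 genes in 293T EglN2, 18561 in 293T KDM5A, 15830 in MDA-MB-231 EglN2 and 16197 in MDA-MB-231 KDM5A. Replicate numbers are shared between groups, but the correlations of residuals between equally numbered libraries were at most 0.0670, and none passed 0.1. The numbers were therefore not read as pairs.

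Counts were rounded to whole numbers and each experiment was fitted on its 9 libraries with edgeR 4.0.16 (TMM scaling, filterByExpr with a count minimum of 10, robust quasi-likelihood fit, two-sided quasi-likelihood F-test). This tested 17622, 17376, 15109 and 15454 genes in 293T EglN2, 293T KDM5A, MDA-MB-231 EglN2 and MDA-MB-231 KDM5A. Each reagent was compared with the controls and reagent 2 with reagent 1. Benjamini-Hochberg adjusted p under 0.05 counted as a call, and a call with both reagents needed the same sign. Both reagents share their controls, so their lists are not independent. CPM values are counts scaled to TMM-adjusted library totals. Expected numbers for independent lists are the product of the list sizes over the genes tested. The difference between cell lines was tested as an interaction in edgeR, with the 18 libraries of a target in 1 fit and the mean of both reagents as the effect.

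A set of 32 gene lists with 920 symbols was fixed, of which 862 were found, 39 of them under an older symbol. Lists with at least 5 measured genes were tested with camera of limma 3.58.1 on the mean effect of both reagents, with a preset correlation between genes of 0.01 and again with an estimated one. Benjamini-Hochberg adjustment ran over all 128 list tests. Counts of members are given for calls with both reagents over all genes and adjusted over the list alone. Overlaps of called genes were tested with Fisher's exact test over genes tested in both experiments, adjusted over 16 overlaps.

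Named genes were taken by a rule, which gave 441 genes. Per experiment it took EGLN1, EGLN2, EGLN3, KDM5A, KDM5B and KDM5C. It took the 10 highest and 10 lowest genes called with both reagents, ranked by the smaller of both log2 fold changes, with a symbol and an average log2 CPM of at least 1. It also took up to 4 members per list and the 5 highest and 5 lowest genes called with all 4 reagents of a set, and genes whose effect differed by a rule set for a closer look. Antisense, unnamed and Y-linked genes were left out, and some genes that the rule took are not reported here.

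The lists, the rule, the tests and the alternatives were set before the data were examined, except where a passage says otherwise. The alternatives were the DESeq2 1.42.0 Wald test, median-of-ratios size factors, no low-count filter, an average log2 CPM of at least 1, the 6 libraries of a comparison alone, a replicate block, an adjusted p under 0.01, a 1.5-fold minimum, each library left out in turn, and for lists fry or a single reagent. Added after seeing the data were the control libraries that stood apart left out, and the genes with the leading 3' UTR match left out. For matches in 3' UTRs, each 7-base sequence carried by at least 100 genes was scored for lower fold changes of its carriers, allowing for UTR length and GC content, and compared with 100 shuffles of the genes.

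The fit was tested on simulated data with the same depths and spread and 200 changed genes, 50 per fold. Among the unchanged genes, 11 to 19 were called for reagent 1 and 0 to 1 for both reagents. A gene with 0 counts in a library may still have up to 3 counts, and intervals of this kind cover counting error only. Software was R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.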

Results

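RNA was sequenced from 36 libraries of 2 established human cell lines, 293T (embryonic kidney) and MDA-MB-231 (breast cancer). In each line, 1 experiment reduced EglN2, a prolyl hydroxylase of the 2-oxoglutarate-dependent family, with siRNA. The other experiment reduced KDM5A, a demethylase of histone H3 lysine 4, with shRNA. Each experiment held 3 controls and 3 libraries for each of 2 reagents. The stated purpose of the series concerns EglN2, hydroxylation of proline 16 on histone H3, KDM5A and H3 lysine 4 trimethylation. The comparisons ask which transcripts changed, whether both reagents changed the same ones, and whether changes after EglN2 and KDM5A knockdown overlapped. Total counts per library ran from 20535514 to 27592132 in 293T EglN2 and from 17176767 to 23417909 in 293T KDM5A. They ran from 14361214 to 18011743 in MDA-MB-231 EglN2 and from 14850582 to 19661501 in MDA-MB-231 KDM5A. Values below are CPM, mean ± SD with n = 3, first in the controls, then with reagent 1 and reagent 2. Log2 fold changes are given in the order reagent 1, reagent 2. The p-values measure only the spread between these samples, since separate cultures are not recorded.

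EGLN2 (GRCh38, chromosome 19, 40798996 to 40808433, plus strand) was lower in all 6 siRNA libraries than in any control of the same line. In 293T it stood at 61.7, 60.2 and 73.7 CPM in the controls, 22.0, 21.9 and 22.1 with siEglN2-1, and 22.2, 22.5 and 22.7 with siEglN2-2. The value of 73.7 came from the control library that carries no replicate number. The log2 fold changes were -1.57 ± 0.07 and -1.54 ± 0.07 (SE), edgeR adjusted p = 3.03e-07 and 3.70e-07. In MDA-MB-231 the controls held 105, 106 and 107 CPM, the siEglN2-1 libraries 25.1, 21.5 and 21.1, and the siEglN2-2 libraries 22.2, 20.8 and 22.1, with log2 fold changes of -2.24 ± 0.05 and -2.29 ± 0.04 (SE) and edgeR adjusted p = 5.79e-36 and 1.97e-36. KDM5A (chromosome 12, 280129 to 389454, minus strand) was lower in all 6 shRNA libraries of each line. In 293T it went from 66.2, 67.6 and 66.6 CPM to 27.6, 27.7 and 26.3 with shKDM5A-1 and 30.9, 32.7 and 31.2 with shKDM5A-2, with log2 fold changes of -1.30 ± 0.05 and -1.08 ± 0.04 (SE) and edgeR adjusted p = 1.56e-22 and 3.91e-21. In MDA-MB-231 it went from 54.9, 48.8 and 47.0 CPM to 16.1, 17.4 and 16.9, and to 19.4, 18.3 and 18.6, with log2 fold changes of -1.57 ± 0.06 and -1.42 ± 0.06 (SE) and edgeR adjusted p = 2.77e-20 and 1.64e-19.

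Related genes were measured beside the targets. After EglN2 siRNA, the hypoxia-sensing hydroxylases EGLN1 and EGLN3 fell in 293T, with log2 fold changes of -0.18 and -0.23 and -0.23 and -0.22, and rose in MDA-MB-231, with 0.19 and 0.21 and 0.60 and 0.55. KDM5A itself fell in MDA-MB-231 EglN2, with -0.19 and -0.17, and did not pass in 293T EglN2, with 0.20 and 0.19 (edgeR adjusted p = 0.191 and 0.228). KDM5B rose in MDA-MB-231 EglN2, with 0.27 and 0.29, and KDM5C did so with 0.09 and 0.13. After KDM5A shRNA in MDA-MB-231, EGLN3 fell from 12.5 ± 1.06 to 6.09 ± 0.713 and 4.75 ± 0.404 CPM, EGLN1 had log2 fold changes of -0.35 and -0.32, and KDM5B of -0.14 and -0.27. In 293T KDM5A, KDM5B rose with shKDM5A-1 and fell with shKDM5A-2, with 0.16 and -0.12, and EGLN1, EGLN2 and EGLN3 had -0.16 and -0.08, 0.06 and 0.16 and -0.19 and -0.10, where at least 1 call per gene was lost when a single library was left out.

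**Figure D1:**
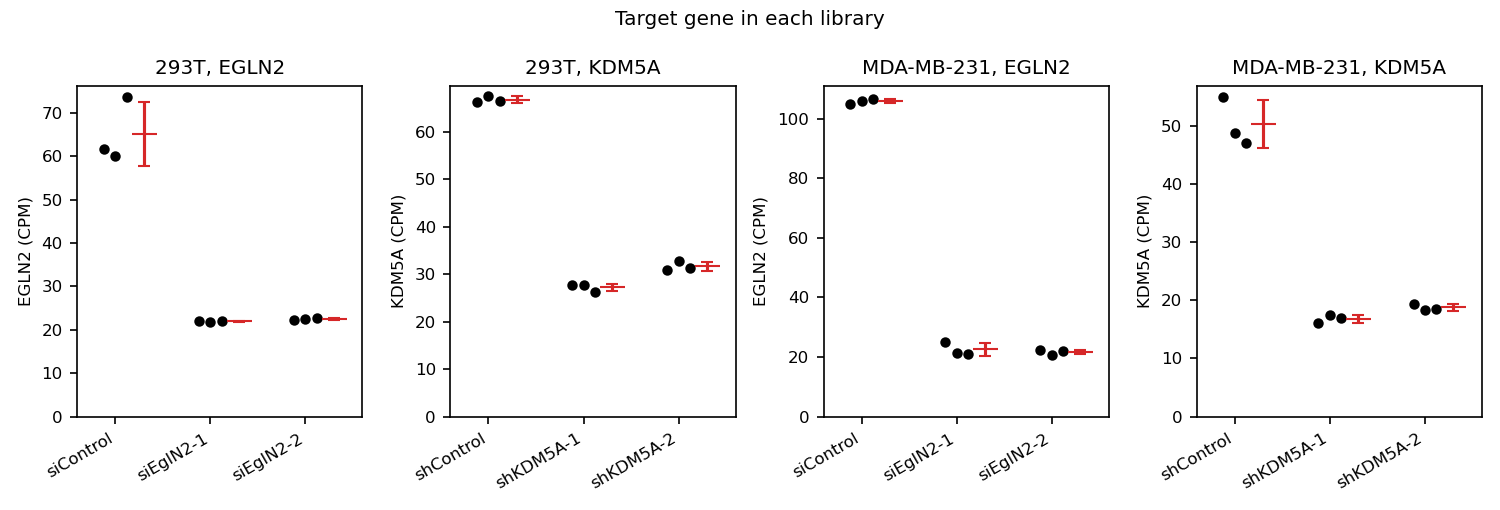
EGLN2 and KDM5A in every library of the experiment that targets each, as CPM on an axis that starts at 0, with 1 point per library and a bar for the mean and SD of each group of 3. The siEglN2 libraries of 293T sit between 21.9 and 22.7 CPM, below controls of 60.2 to 73.7 CPM.

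In 293T cells given either EglN2 siRNA, cholesterol synthesis genes, immediate early genes and hypoxia targets fell, and targets of the stress regulator ATF4 rose. EIF4H, which encodes a translation initiation factor, fell from 473 ± 6.66 CPM in the controls to 119 ± 1.60 and 120.5 ± 3.14 CPM (log2 fold changes -1.99 ± 0.04 and -1.97 ± 0.04 (SE), edgeR adjusted p = 5.23e-10 and 5.72e-10). ORMDL3, a regulator of sphingolipid synthesis, fell from 34.2 ± 1.41 to 10.2 ± 1.36 and 10.6 ± 1.11 CPM. The transcription factor MYB went from 12.1 ± 0.978 to 4.18 ± 0.0375 and 3.99 ± 0.634 CPM. Among the genes that rose, SGPL1, the sphingosine phosphate lyase, went from 30.7 ± 3.98 to 97.1 ± 2.72 and 96.5 ± 3.17 CPM. The kinase PSKH1 went from 13.5 ± 0.855 to 45.4 ± 1.32 and 44.2 ± 2.81 CPM. The presynaptic genes BSN and SYP went from 4.54 ± 0.640 to 17.8 ± 0.0828 and 17.2 ± 1.48 CPM and from 7.21 ± 0.594 to 23.5 ± 1.36 and 22.4 ± 0.397 CPM. SFT2D3 had 0 counts in the 3 controls and 239 and 225 counts over the 3 libraries of each siRNA (3.44 ± 1.06 and 3.19 ± 0.267 CPM), at least 80.7- and 74.8-fold higher than a floor of 3 counts over the control group. FUT1, GABRD, PRTG, RAB39A and TMEM145 also stood among the 10 highest, with log2 fold changes of 2.23 and 2.10, 1.81 and 1.85, 1.75 and 1.77, 1.67 and 1.72 and 1.69 and 1.73. The 10 lowest further held FOS, FKBP1B, PKI55, NTAN1 and SIVA1, with -1.58 and -1.46, -1.52 and -1.52, -1.47 and -1.46, -1.34 and -1.35 and -1.33 and -1.32, and SLX1A, whose reads are shared with a near-identical copy and whose value is uncertain, with -1.58 and -1.47. The 3' UTRs of EIF4H, ORMDL3, MYB and FKBP1B, 4 of the 9 lowest genes with an annotated one, held the 7-base match GACAGAA, against 1 of the 10 highest, SYP; this was looked up after the values were seen.

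Of the cholesterol synthesis and SREBP2 targets, 18 of 25 measured members fell and 3 rose (19 and 3 adjusted over the list alone), with a median log2 fold change of -0.27 (camera adjusted p = 6.58e-08, adjusted p = 0.00952 with an estimated correlation). IDI1 fell from 112 ± 7.72 to 59.6 ± 0.444 and 62.2 ± 2.22 CPM, and SQLE, INSIG1 and MSMO1 had log2 fold changes of -0.62 and -0.63, -0.56 and -0.58 and -0.56 and -0.62. Among immediate early genes, 12 of 26 measured members fell and 0 rose (13 and 1 adjusted over the list alone). The median was -0.37 (camera adjusted p = 7.87e-08, adjusted p = 0.0144 with an estimated correlation), with BTG2 at -0.86 and -0.92 and FOSB at -0.99 and -1.12. For hypoxia and HIF targets, 21 of 35 measured members fell and 3 rose (22 and 3 adjusted over the list alone). The median was -0.23 (camera adjusted p = 2.59e-05, adjusted p = 0.0176 with an estimated correlation). These included ENO1, a glycolytic enzyme, from 2511 ± 187 to 1829 ± 11.3 and 1834 ± 10.5 CPM. NDRG1 went from 131 ± 1.22 to 95.7 ± 1.59 and 95.4 ± 2.46 CPM, and ANKRD37 and HK2 had -0.66 and -0.71 and -0.46 and -0.45. In the ATF4 list, 19 of 33 measured members rose and 1 fell (20 and 1 adjusted over the list alone). The median was 0.16 (camera adjusted p = 4.10e-06, adjusted p = 0.0488 with an estimated correlation). SLC7A11, the cystine transporter, rose from 41.5 ± 6.73 to 84.5 ± 2.55 and 79.8 ± 4.18 CPM. CHAC1 went from 22.8 ± 2.02 to 41.4 ± 2.41 and 39.8 ± 0.765 CPM, and NUPR1 and PCK2 had 1.08 and 1.14 and 0.64 and 0.68.

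A further 5 lists of 293T EglN2 passed with the preset correlation and lost the call with an estimated one. In MYC and ribosome biogenesis, 15 of 32 measured members fell and 1 rose (18 and 1 adjusted over the list alone). The median was -0.20 (camera adjusted p = 2.98e-05, adjusted p = 0.221 with an estimated correlation), with MYC from 357 ± 4.73 to 233 ± 3.72 and 233 ± 1.75 CPM and NOLC1 and FBL at -0.39 and -0.41 and -0.40 and -0.37. Of cytosolic ribosomal proteins, 6 of 37 measured members fell and 0 rose (1 and 0 adjusted over the list alone) (camera adjusted p = 0.00511, adjusted p = 0.730 with an estimated correlation), with RPS3 at -0.56 and -0.53. In the respiratory chain, 12 of 38 measured members fell and 3 rose (14 and 3 adjusted over the list alone) (camera adjusted p = 0.00588, adjusted p = 0.730 with an estimated correlation), with SDHA at -0.37 and -0.35, and in mitochondrial ribosome and import, 13 of 31 measured members fell and 3 rose (16 and 4 adjusted over the list alone) (camera adjusted p = 0.0340, adjusted p = 0.730 with an estimated correlation), with HSPE1 at -0.49 and -0.54. Without the unnumbered control library, the camera adjusted p of these last 3 lists was 0.0725, 0.151 and 0.123. With a replicate block, which also leaves that library out, it was 0.169, 0.2002 and 0.2003. Among replication-dependent histone genes, 4 of 12 measured members rose and 0 fell (4 and 0 adjusted over the list alone). The median was 0.45 (camera adjusted p = 0.0384, adjusted p = 0.168 with an estimated correlation), a call that was also lost without siControl 1 (0.0764), siControl 2 (0.0857), the unnumbered control (0.0669) or siEglN2-1 replicate 3 (0.0558) and with the replicate block (0.0587). Reads of these genes are shared between near-identical copies, so their values are uncertain. Mitochondrial transcripts took 5.36 ± 0.0878% of counts in the controls and 6.88 ± 0.180% and 6.59 ± 0.112% with the siRNAs.

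Camera (limma) did not call the other 23 lists of 293T EglN2. Its adjusted p was 0.0565 for neuronal genes, 0.0575 for 2-oxoglutarate oxygenases, 0.141 for H3K4 methyltransferase and demethylase genes and 0.195 for S phase. It was 0.196 for lysosome, 0.215 for Wnt targets, 0.231 for centrosome and 0.322 for both germline genes and the unfolded protein response. KDM5A partner complexes had 0.467, TGF-beta and YAP targets 0.544, 293T markers 0.545, NF-kB 0.644 and matrix genes 0.652. MDA-MB-231 markers and markers of other cell types had 0.708, NRF2 targets 0.729, p53 targets 0.767 and interferon-stimulated genes 0.777. Mitosis had 0.813, FOXO targets 0.841, Wnt components 0.877 and epithelial genes 0.984. Within these lists, E2F1 and RRM2 of S phase rose, with log2 fold changes of 0.84 and 0.88 and 0.97 and 0.98, and DUT fell, with -0.80 and -0.86. Of the H3K4 list, 8 of 23 measured members fell and 3 rose (8 and 3 adjusted over the list alone), among them SETD7 with 0.46 and 0.46, and SMYD2 and KDM1B with -1.09 and -1.14 and -0.58 and -0.68. The neuronal list passed without siEglN2-1 replicate 1 (0.0412), siEglN2-1 replicate 3 (0.0498) or siEglN2-2 replicate 2 (0.0430), and the oxygenase list without the unnumbered control (0.0216) or with the replicate block (0.0218).

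edgeR called 6190 of 17622 genes with siEglN2-1 (2981 higher, 3209 lower) and 6019 with siEglN2-2 (2968 higher, 3051 lower). With both siRNAs, 2566 genes were higher and 2740 lower, where independent lists would share 502 and 556, and 0 were called in opposite directions. Part of this excess may come from the shared controls, which cannot be split into groups of at least 2. Across genes the log2 fold changes of the siRNAs had r = 0.819 and a covariance of 0.181, against r = 0.513, a covariance of 0.0448 and 0 shared genes in data simulated with shared controls and no effect. Of genes changed 1.5-fold, 2-fold and 4-fold in simulated data, 64%, 78% and 92% were called with both reagents. Between the siRNAs edgeR called 0 genes, with 276 (1.57%) at an unadjusted p under 0.05, DESeq2 called 1, and a 1.5-fold difference was recovered for 60% of genes in simulated data. Without the unnumbered control that count was 4, and without siEglN2-1 replicate 1 it was 1. The unnumbered control stood apart from the other controls (chi-square per degree of freedom 19.2 and 22.8 against 2.02 between those). Simulated controls may lack this spread, so the simulated covariance may be too low.

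In MDA-MB-231 cells given either EglN2 siRNA, genes of mitosis and S phase fell, inflammatory cytokine genes moved both ways, and interferon-stimulated genes rose. EIF4H fell from 430.4 ± 4.45 CPM in the controls to 91.7 ± 3.30 and 91.5 ± 1.71 CPM (log2 fold changes -2.23 ± 0.02 and -2.23 ± 0.02 (SE), edgeR adjusted p = 2.48e-46 and 1.81e-46). The cytokine genes IL1B and CSF2 fell from 19.1 ± 0.979 to 4.61 ± 0.554 and 4.16 ± 0.362 CPM and from 22.6 ± 0.186 to 6.46 ± 0.396 and 6.02 ± 0.386 CPM. The EGF receptor ligand EREG went from 48.1 ± 3.78 to 14.8 ± 0.365 and 14.6 ± 0.708 CPM. The nucleoside transporter SLC29A1 went from 241 ± 2.36 to 72.7 ± 3.22 and 76.3 ± 0.7499 CPM. CLDND1 went from 229 ± 5.91 to 61.3 ± 0.923 and 59.7 ± 1.69 CPM. HTR7, ORMDL3 and S100A2 completed the lowest, with log2 fold changes of -1.84 and -1.91, -1.69 and -1.59 and -1.63 and -1.54. Among the highest, PSKH1 rose from 14.3 ± 1.59 to 44.4 ± 1.39 and 43.6 ± 0.774 CPM. CHORDC1 went from 40.9 ± 2.29 to 107 ± 3.16 and 105 ± 3.05 CPM. The interleukin 7 receptor gene IL7R went from 7.61 ± 0.707 to 19.2 ± 0.453 and 19.2 ± 0.574 CPM. SYNPO went from 16.7 ± 0.511 to 41.4 ± 1.19 and 43.1 ± 1.62 CPM. TNFSF18, NEK11, CST7, OXTR and C9orf41 had 1.80 and 1.76, 1.59 and 1.55, 1.55 and 1.54, 1.45 and 1.47 and 1.37 and 1.36, and KRTAP2-3, which shares reads with related genes, had 1.95 and 1.92. The match GACAGAA stood in the 3' UTRs of EIF4H, IL1B, CLDND1, HTR7, CSF2, SLC29A1 and ORMDL3, 7 of the 10 lowest, and of 0 of the 10 highest, again looked up afterwards.

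Of the mitosis and G2/M genes, 31 of 35 measured members fell and 1 rose (31 and 1 adjusted over the list alone). The median was -0.22 (camera adjusted p = 3.58e-12, adjusted p = 0.00860 with an estimated correlation). The proliferation marker MKI67 fell from 316 ± 8.35 to 162 ± 1.60 and 168 ± 3.41 CPM, and BIRC5, CENPF and KIF23 had log2 fold changes of -0.53 and -0.51, -0.45 and -0.49 and -0.45 and -0.47. In S phase and E2F targets, 25 of 36 measured members fell and 3 rose (27 and 3 adjusted over the list alone). The median was -0.19 (camera adjusted p = 1.70e-07, adjusted p = 0.00952 with an estimated correlation), with DUT, GINS2 and CDC45 at -0.74 and -0.81, -0.63 and -0.66 and -0.54 and -0.59, while the cyclin gene CCNE2 rose, with 0.62 and 0.70. Among interferon-stimulated genes, 21 of 37 measured members rose and 2 fell (21 and 2 adjusted over the list alone). The median was 0.22 (camera adjusted p = 7.08e-05, adjusted p = 0.0185 with an estimated correlation). IFIT2 rose from 42.6 ± 3.38 to 65.7 ± 1.99 and 65.1 ± 1.31 CPM. IFIT3 went from 77.00 ± 2.42 to 117 ± 1.16 and 119.7 ± 0.524 CPM, and CXCL10 and OASL had 1.28 and 1.14 and 0.73 and 0.77. For immediate early genes, 15 of 27 measured members fell and 4 rose (15 and 4 adjusted over the list alone). The median was -0.15 (camera adjusted p = 0.00111, adjusted p = 0.0375 with an estimated correlation), with FOS from 29.1 ± 2.67 to 11.6 ± 1.65 and 11.04 ± 0.293 CPM and KLF2 and EGR1 at -1.11 and -1.08 and -0.75 and -0.64. Of the MDA-MB-231 marker genes, 15 of 25 measured members fell and 5 rose (15 and 5 adjusted over the list alone). The median was -0.11 (camera adjusted p = 0.00286, adjusted p = 0.0494 with an estimated correlation), with the protease gene PLAU from 383 ± 2.27 to 238 ± 5.22 and 238 ± 2.84 CPM and S100A4 at -0.65 and -0.74.

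The remaining 5 called lists of MDA-MB-231 EglN2 lost the call with an estimated correlation. In the unfolded protein response, 18 of 27 measured members fell and 4 rose (18 and 4 adjusted over the list alone). The median was -0.23 (camera adjusted p = 2.03e-05, adjusted p = 0.131 with an estimated correlation), with the ER chaperone gene CANX from 1205 ± 30.4 to 664 ± 9.55 and 664 ± 1.51 CPM and PDIA4 at -0.55 and -0.53. For centrosome and centriole genes, 11 of 23 measured members fell and 1 rose (11 and 1 adjusted over the list alone) (camera adjusted p = 0.00374, adjusted p = 0.236 with an estimated correlation), with PLK4 and STIL at -0.52 and -0.45 and -0.31 and -0.33. In lysosome and autophagy, 14 of 31 measured members rose and 2 fell (15 and 3 adjusted over the list alone) (camera adjusted p = 0.00403, adjusted p = 0.112 with an estimated correlation), with RRAGD and NEU1 at 0.65 and 0.52 and 0.43 and 0.39 and the protease gene CTSD at -0.40 and -0.41. Of cholesterol synthesis genes, 12 of 26 measured members fell and 3 rose (12 and 3 adjusted over the list alone) (camera adjusted p = 0.00916, adjusted p = 0.220 with an estimated correlation). Among NF-kB and inflammatory cytokine genes, 14 of 25 measured members fell and 8 rose (14 and 8 adjusted over the list alone). The median was -0.30 (camera adjusted p = 0.0128, adjusted p = 0.101 with an estimated correlation). CSF3 fell from 24.6 ± 0.185 to 10.3 ± 0.767 and 10.9 ± 0.999 CPM, while ICAM1, an adhesion molecule, rose from 70.05 ± 1.33 to 158 ± 3.93 and 159 ± 4.33 CPM. Mitochondrial transcripts took 8.87 ± 0.0586% of counts in the controls and 9.33 ± 0.103% and 9.24 ± 0.163% with the siRNAs.

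The other 22 lists of MDA-MB-231 EglN2 were not called. Camera (limma) gave an adjusted p of 0.0511 for FOXO targets, 0.0761 for cytosolic ribosomal proteins, 0.0762 for TGF-beta and YAP targets and 0.141 for 293T markers. Histone genes had 0.186, NRF2 targets 0.285, epithelial genes 0.320, the respiratory chain 0.327 and neuronal genes 0.342. Oxygenases had 0.362, matrix genes 0.366, markers of other cell types 0.398 and MYC and ribosome biogenesis 0.563. The H3K4 list and mitochondrial ribosome had 0.580, KDM5A partners and p53 targets 0.652 and hypoxia targets 0.729. ATF4 targets had 0.777, Wnt targets 0.877, and germline genes and Wnt components 0.897. Members of these lists still changed in both directions. VEGFA fell from 507 ± 5.63 to 297 ± 6.15 and 295 ± 3.62 CPM. The collagen hydroxylase gene PLOD2 went from 201 ± 3.94 to 308 ± 8.79 and 299.7 ± 5.58 CPM, and among TGF-beta and YAP targets THBS1 and ANKRD1 rose from 430.5 ± 19.2 to 789 ± 7.33 and 807 ± 20.9 CPM and from 276 ± 4.08 to 494 ± 7.11 and 491 ± 5.91 CPM. DKK1, an inhibitor of Wnt signalling, rose from 207 ± 5.30 to 405 ± 5.46 and 395 ± 4.92 CPM. The FOXO list passed without siEglN2-1 replicate 1 (0.0374) or 2 (0.0459) or without siEglN2-2 replicate 1 (0.0455), 2 (0.0479) or 3 (0.0444). Without siControl 1 the ribosomal protein list (0.0492), the TGF-beta list (3.75e-04) and the NRF2 list (0.0370) passed, and the TGF-beta list did so without siControl 3 (0.0364).

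edgeR called 6725 of 15109 genes with siEglN2-1 (3249 higher, 3476 lower) and 6859 with siEglN2-2 (3295 higher, 3564 lower). Both siRNAs raised 2769 and lowered 3079 of these, against 709 and 820 for independent lists, and 0 genes were called in opposite directions. Part of this excess may again come from the shared controls, since the covariance of the log2 fold changes was 0.130 (r = 0.813), and 0.0379 (r = 0.505) in data simulated without an effect, where 2 genes were shared. In simulated data with changed genes, 68%, 78% and 92% of those changed 1.5-fold, 2-fold and 4-fold were called with both. Between the siRNAs 1 gene was called, RP4-798P15.3, named after its values were seen, with 940 (6.22%) at an unadjusted p under 0.05, and DESeq2 also called 1. That count was 0 without siControl 1, 2 without siControl 2, siEglN2-1 replicate 3 or siEglN2-2 replicate 2, 5 without siControl 3 or siEglN2-2 replicate 1, and 7 without siEglN2-1 replicate 1. Here siControl 1 stood apart from the other controls, with a chi-square per degree of freedom of 6.72 and 7.66 against 1.57.

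In 293T, S phase, MYC and ribosome biogenesis and mitochondrial ribosome lists rose and the matrix list fell with either KDM5A shRNA. Many members did not. G0S2, which encodes an inhibitor of triglyceride lipolysis, fell from 40.5 ± 0.797 CPM in the controls to 9.26 ± 1.01 and 10.8 ± 0.447 CPM (log2 fold changes -2.13 ± 0.07 and -1.90 ± 0.06 (SE), edgeR adjusted p = 8.23e-24 and 2.46e-23). The growth factor gene IGF2 fell from 7.57 ± 0.577 to 2.45 ± 0.0986 and 3.01 ± 0.178 CPM. The chaperone gene CLU went from 27.6 ± 0.958 to 10.3 ± 0.555 and 11.6 ± 0.427 CPM and the matrix gene TNC from 5.55 ± 0.0763 to 2.35 ± 0.381 and 1.53 ± 0.225 CPM. HKR1 (-1.13 and -1.35), PHLDA2 (-0.99 and -1.24), APOBEC3B and INHBE were also among the lowest. Rises were smaller. The transcription factor gene ETV4 went from 1.22 ± 0.203 to 2.19 ± 0.524 and 3.80 ± 0.488 CPM. GADD45B went from 8.47 ± 1.03 to 11.9 ± 0.745 and 11.8 ± 0.548 CPM, and RAPGEFL1 and SKIDA1 had 0.77 and 0.57 and 0.53 and 0.53. GALNT4 fell (-1.13 and -1.55) and the POC1B-GALNT4 read-through transcript rose (1.75 and 1.19), but they share reads, so both are uncertain. Of the 10 lowest only TNC, and of the 10 highest ZNF117 and NPIPB11, held 3' UTR matches that led the falls with these shRNAs.

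Of the S phase and E2F targets, 20 of 36 measured members rose and 0 fell (20 and 0 adjusted over the list alone). The median was 0.15 (camera adjusted p = 1.40e-14, adjusted p = 0.00333 with an estimated correlation). UHRF1, a maintenance factor of DNA methylation, rose from 122 ± 3.02 to 158 ± 4.31 and 147 ± 1.32 CPM, and CCNE2, E2F1 and FEN1 had log2 fold changes of 0.50 and 0.36, 0.25 and 0.36 and 0.30 and 0.29. In MYC and ribosome biogenesis, 14 of 32 measured members rose and 0 fell (16 and 0 adjusted over the list alone). The median was 0.17 (camera adjusted p = 6.15e-12, adjusted p = 0.0375 with an estimated correlation), with NME1 and MYBBP1A at 0.26 and 0.25 and 0.30 and 0.20. For mitochondrial ribosome and import, 12 of 31 measured members rose and 0 fell (13 and 0 adjusted over the list alone). The median was 0.12 (camera adjusted p = 1.65e-07, adjusted p = 0.0268 with an estimated correlation), with MRPS7 and HSPD1 at 0.32 and 0.31 and 0.19 and 0.22. Among matrix genes, 7 of 34 measured members fell and 0 rose (7 and 0 adjusted over the list alone). The median was -0.30 (camera adjusted p = 1.29e-12, adjusted p = 0.00952 with an estimated correlation), while another 7 went in opposite directions. Fibronectin, FN1, fell from 59.5 ± 1.49 to 35.8 ± 1.31 and 47.2 ± 1.57 CPM. The integrin gene ITGB1 went from 164 ± 1.03 to 118 ± 1.51 and 66.7 ± 1.10 CPM, and LOXL2 had -0.72 and -0.53. Of hypoxia targets, 9 of 35 measured members fell and 2 rose (11 and 2 adjusted over the list alone). The median was -0.11 (camera adjusted p = 1.30e-07, adjusted p = 0.00952 with an estimated correlation), with NDRG1 from 191 ± 5.89 to 160.0 ± 2.54 and 112 ± 3.05 CPM and P4HA1 and P4HA2 at -0.29 and -0.56 and -0.33 and -0.34.

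Another 5 lists of 293T KDM5A lost the call with an estimated correlation. Of cytosolic ribosomal proteins, 12 of 37 measured members rose and 0 fell (12 and 0 adjusted over the list alone). The median was 0.08 (camera adjusted p = 3.92e-10, adjusted p = 0.321 with an estimated correlation), and with shKDM5A-2 alone camera gave 0.210. Among MDA-MB-231 markers, 5 of 16 measured members fell and 0 rose (5 and 0 adjusted over the list alone) (camera adjusted p = 3.38e-05, adjusted p = 0.0560 with an estimated correlation), with ANXA1 from 13.6 ± 1.11 to 7.002 ± 0.598 and 1.08 ± 0.0807 CPM. In p53 targets, 3 of 28 measured members rose and 0 fell (3 and 0 adjusted over the list alone), while 8 went in opposite directions (camera adjusted p = 0.00850, adjusted p = 0.109 with an estimated correlation), and the direction was down with shKDM5A-1 alone (0.146) and up with shKDM5A-2 (1.35e-10). CDKN1A, a cell cycle inhibitor, fell and then rose between the shRNAs, from 54.9 ± 1.19 to 33.5 ± 0.308 and 65.5 ± 0.258 CPM. For mitosis and G2/M, 4 of 35 measured members fell and 0 rose (4 and 0 adjusted over the list alone) (camera adjusted p = 0.0290, adjusted p = 0.101 with an estimated correlation), and shKDM5A-1 alone gave 0.766. In the ATF4 list, 7 of 33 measured members fell and 3 rose (7 and 3 adjusted over the list alone) (camera adjusted p = 0.0308, adjusted p = 0.236 with an estimated correlation), with a rise for shKDM5A-1 alone (7.06e-06) and a fall for shKDM5A-2 (4.36e-16). More ATF4 members, 10, were called in opposite directions than fell with both. Opposite calls also numbered 7 in MYC and ribosome biogenesis, 6 in S phase, 5 in ribosomal proteins, 4 in hypoxia targets, 3 in mitosis, 1 in mitochondrial ribosome and 0 in MDA-MB-231 markers. Mitochondrial transcripts took 4.21 ± 0.0131% of counts in the controls and 3.94 ± 0.0330% and 3.80 ± 0.0945% with the shRNAs.

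In 293T KDM5A, 22 lists were not called. Adjusted p from camera (limma) was 0.0518 for oxygenases, 0.0637 for the respiratory chain, 0.138 for the H3K4 list and 0.236 for Wnt targets. Epithelial genes had 0.265, the unfolded protein response 0.291, neuronal genes 0.362, Wnt components 0.559 and FOXO targets 0.580. Markers of other cell types had 0.673, centrosome 0.695, KDM5A partners 0.726, TGF-beta and YAP targets 0.749, and 293T markers and immediate early genes 0.777. NRF2 targets had 0.845, NF-kB 0.846, histone genes 0.885, cholesterol 0.912, interferon-stimulated genes and lysosome 0.923, and germline genes 0.999. Each shRNA alone called neuronal genes (down with shKDM5A-1, 3.32e-07, up with shKDM5A-2, 8.95e-05) and histone genes (down, 0.0330, and up, 0.00629) in opposite directions. Of neuronal genes and of Wnt targets 8 each went in opposite directions. The oxygenase list passed without shKDM5A-1 replicate 1 (0.0490) or 3 (0.0496), shKDM5A-2 replicate 2 (0.0378), shControl 1 (0.0481) or shControl 3 (0.0446). The respiratory chain passed without shKDM5A-1 replicate 1 (0.0434) or 3 (0.0496), shKDM5A-2 replicate 2 (0.0390) or shControl 3 (0.0192).

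edgeR called 7340 of 17376 genes with shKDM5A-1 (3755 higher, 3585 lower) and 6777 with shKDM5A-2 (3396 higher, 3381 lower). Both shRNAs raised 1274 and lowered 1062 genes, against 734 and 698 for independent lists, while 1493 genes moved in opposite directions, against 1431. Part of the excess may come from the shared controls. The covariance was 0.0588 (r = 0.339, same sign 56.6%), and 0.0493 (r = 0.487, 66.3%) simulated without an effect, with 0 genes shared. Signs agreed less than simulated. Opposite calls included SNAI2 (0.22 and -1.42), MTA2 (-0.82 and 0.17) and KLF6 (0.18 and -0.57). Between the shRNAs edgeR called 8569 genes (4230 higher and 4339 lower with shKDM5A-2). Of simulated 1.5-, 2- and 4-fold changes, 66%, 78% and 90% were called with both.

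In MDA-MB-231 cells given KDM5A shRNA, inflammatory cytokine genes, hypoxia targets and interferon-stimulated genes fell, and genes of MYC and ribosome biogenesis rose. The mucin gene MUC5AC fell from 27.8 ± 1.61 CPM in the controls to 1.79 ± 0.573 and 1.49 ± 0.440 CPM (log2 fold changes -3.95 ± 0.13 and -4.23 ± 0.14 (SE), edgeR adjusted p = 1.51e-20 and 3.97e-21), and its neighbour MUC5B from 29.03 ± 2.73 to 2.62 ± 0.0931 and 0.896 ± 0.247 CPM. The chemokine gene CXCL10 fell from 7.36 ± 0.156 to 0.939 ± 0.111 and 0.881 ± 0.174 CPM, the costimulatory ligand gene ICOSLG, whose 3' UTR held 1 of the matches that led the falls with these shRNAs, from 16.5 ± 1.05 to 1.66 ± 0.381 and 1.07 ± 0.111 CPM. C15orf48 went from 74.6 ± 2.25 to 15.2 ± 1.10 and 11.8 ± 0.528 CPM. SAA1 and SAA2, which share reads, had -2.53 and -3.01 and -2.36 and -2.97. LEFTY1 stood at 6.91 CPM in the controls, 1.47 with shKDM5A-1 and 0.0720 with shKDM5A-2. Among the genes that rose, CYP1A1, a target of the aryl hydrocarbon receptor, went from 5.46 ± 0.158 to 15.5 ± 0.735 and 20.2 ± 1.91 CPM, and RGS4, ADAMTS6, SH2D5, FAM196B, PLCXD1 and ST6GALNAC5 had 1.16 and 1.74, 1.16 and 1.73, 1.41 and 1.45, 1.31 and 1.33, 1.14 and 1.67 and 1.29 and 2.05. Of these, SH2D5 and PLCXD1 also held such a match. HSPA6, KRTAP2-3 and FAM86B1, whose reads are shared with related genes, had 2.37 and 3.55, 1.52 and 2.68 and 1.30 and 1.40.

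Of the NF-kB and inflammatory cytokine genes, 24 of 27 measured members fell and 0 rose (24 and 0 adjusted over the list alone). The median was -1.23 (camera adjusted p = 1.99e-87, adjusted p = 0.00333 with an estimated correlation). CXCL8 fell from 872 ± 28.8 CPM in the controls to 228 ± 4.11 and 151 ± 3.55 CPM. CSF2 went from 77.96 ± 3.48 to 14.7 ± 1.02 and 9.39 ± 0.573 CPM. CSF3 went from 182 ± 3.50 to 38.1 ± 1.14 and 41.6 ± 3.08 CPM. IL6 went from 93.9 ± 1.22 to 33.1 ± 0.590 and 22.1 ± 1.30 CPM. CXCL1 went from 203 ± 2.50 to 50.7 ± 1.65 and 42.01 ± 1.08 CPM. In hypoxia and HIF targets, 31 of 37 measured members fell and 0 rose (31 and 0 adjusted over the list alone). The median was -0.72 (camera adjusted p = 2.04e-48, adjusted p = 0.00333 with an estimated correlation). The carbonic anhydrase genes CA9 and CA12 fell from 5.20 ± 0.524 to 1.73 ± 0.153 and 0.680 ± 0.273 CPM and from 112 ± 1.82 to 50.4 ± 1.51 and 32.1 ± 1.15 CPM. NDRG1 went from 404 ± 5.03 to 154 ± 2.61 and 83.99 ± 3.19 CPM. The lysyl oxidase gene LOX went from 109 ± 4.19 to 49.5 ± 0.570 and 38.96 ± 2.45 CPM. For MYC and ribosome biogenesis, 24 of 32 measured members rose and 0 fell (24 and 0 adjusted over the list alone). The median was 0.34 (camera adjusted p = 2.90e-14, adjusted p = 0.0363 with an estimated correlation), with WDR43 from 107 ± 2.38 to 155 ± 1.27 and 144 ± 2.83 CPM and MRTO4 and POLR1B at 0.72 and 0.62 and 0.65 and 0.51. Of MDA-MB-231 markers, which share IL6 and CXCL8 with the NF-kB list, 14 of 25 measured members fell and 5 rose (14 and 5 adjusted over the list alone). The median was -0.37 (camera adjusted p = 1.62e-11, adjusted p = 0.00677 with an estimated correlation), with S100A4 at -0.98 and -1.29. Among interferon-stimulated genes, 23 of 37 measured members fell and 2 rose (24 and 2 adjusted over the list alone). The median was -0.43 (camera adjusted p = 3.30e-06, adjusted p = 0.0138 with an estimated correlation), with OAS1 and ISG20 at -0.79 and -0.89 and -0.78 and -1.42.

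In the unfolded protein response, 19 of 27 measured members fell and 1 rose (19 and 1 adjusted over the list alone). The median was -0.29 (camera adjusted p = 3.40e-07, adjusted p = 0.0144 with an estimated correlation), with HSP90B1 from 1454 ± 29.8 to 1008 ± 8.53 and 1055 ± 20.6 CPM. Of immediate early genes, 13 of 27 measured members fell and 2 rose (13 and 2 adjusted over the list alone). The median was -0.15 (camera adjusted p = 3.30e-06, adjusted p = 0.0221 with an estimated correlation), with FOS from 61.6 ± 1.09 to 29.8 ± 1.10 and 9.45 ± 0.660 CPM. Among cholesterol synthesis genes, 7 of 26 measured members fell and 0 rose (7 and 1 adjusted over the list alone). The median was -0.24 (camera adjusted p = 1.92e-06, adjusted p = 0.0138 with an estimated correlation), while with shKDM5A-1 alone the direction was up (0.806) and with shKDM5A-2 down (4.36e-16). For TGF-beta and YAP targets, 12 of 28 measured members rose and 7 fell (12 and 7 adjusted over the list alone). The median was 0.10 (camera adjusted p = 4.02e-06, adjusted p = 0.0185 with an estimated correlation). The YAP targets CTGF and CYR61 rose from 169.7 ± 2.47 to 308 ± 1.14 and 459 ± 2.21 CPM and from 483 ± 6.58 to 848 ± 5.62 and 782 ± 5.31 CPM. The tissue factor gene F3 went from 192 ± 4.31 to 627 ± 9.18 and 321 ± 6.13 CPM.

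The 8 other called lists of MDA-MB-231 KDM5A lost the call with an estimated correlation. In mitochondrial ribosome and import, 21 of 31 measured members rose and 0 fell (21 and 0 adjusted over the list alone). The median was 0.26 (camera adjusted p = 6.34e-08, adjusted p = 0.101 with an estimated correlation), with TIMM44 at 0.50 and 0.47. Of histone genes, 3 of 13 measured members rose and 0 fell (3 and 0 adjusted over the list alone) (camera adjusted p = 0.00374, adjusted p = 0.0640 with an estimated correlation), with 0.415 for shKDM5A-1 alone. Among mitosis genes, 8 of 35 measured members rose and 1 fell (8 and 1 adjusted over the list alone) (camera adjusted p = 0.00471, adjusted p = 0.168 with an estimated correlation), with KIF23 at 0.39 and 0.42, and with shKDM5A-2 alone the direction was down (0.964). For metallothionein and NRF2 targets, 9 of 22 measured members fell and 3 rose (10 and 3 adjusted over the list alone) (camera adjusted p = 0.00832, adjusted p = 0.101 with an estimated correlation), with FTH1 at -0.46 and -0.90 and 0.496 for shKDM5A-1 alone. Of ATF4 targets, 11 of 32 measured members rose and 5 fell (11 and 5 adjusted over the list alone) (camera adjusted p = 0.0111, adjusted p = 0.101 with an estimated correlation), with PPP1R15A from 94.1 ± 3.76 to 181 ± 6.28 and 178 ± 4.04 CPM and 0.956 for shKDM5A-1 alone. In epithelial genes, 5 of 21 measured members fell and 2 rose (5 and 2 adjusted over the list alone) (camera adjusted p = 0.0269, adjusted p = 0.109 with an estimated correlation), with JUP at -1.14 and -1.66, and the direction was up with shKDM5A-1 alone (0.992). Of oxygenases, 9 of 34 measured members fell and 6 rose (11 and 6 adjusted over the list alone) (camera adjusted p = 0.0290, adjusted p = 0.155 with an estimated correlation), with PLOD2 from 361 ± 18.1 to 199 ± 0.395 and 108 ± 1.85 CPM and KDM3A at -0.55 and -0.71. Among matrix genes, 17 of 36 measured members fell and 11 rose (17 and 11 adjusted over the list alone) (camera adjusted p = 0.0305, adjusted p = 0.101 with an estimated correlation), with FN1 from 626 ± 8.71 to 313 ± 7.68 and 334 ± 6.93 CPM and SPARC at -1.51 and -1.38. Among the called lists of this experiment, members called in opposite directions numbered 7 in mitosis and in ATF4 targets, 6 in cholesterol synthesis and in epithelial genes, 4 in immediate early genes, 3 in MDA-MB-231 markers and at most 2 in each other list. Mitochondrial transcripts took 7.69 ± 0.0273% of counts in the controls and 9.16 ± 0.0621% and 9.75 ± 0.121% with the shRNAs.

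Camera (limma) left 15 lists of MDA-MB-231 KDM5A uncalled. S phase had an adjusted p of 0.0565, 293T markers 0.131, cytosolic ribosomal proteins 0.140, neuronal genes 0.159 and Wnt targets 0.172. Lysosome had 0.270, FOXO targets 0.308 and the respiratory chain 0.320. Centrosome genes had 0.327, markers of other cell types 0.362, Wnt components 0.390, germline genes 0.560, the H3K4 list 0.777, p53 targets 0.839 and KDM5A partners 0.885. Of 37 ribosomal protein genes, 28 went in opposite directions with the 2 shRNAs, such as RPL19, with 0.18 and -0.52, and the list rose with shKDM5A-1 alone (3.63e-11) and fell with shKDM5A-2 (0.00629). Of the H3K4 list, 5 of 23 measured members fell and 5 rose (5 and 5 adjusted over the list alone), with WDR5 at 0.34 and 0.42.

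edgeR called 8548 of 15454 genes with shKDM5A-1 (4348 higher, 4200 lower) and 9120 with shKDM5A-2 (4540 higher, 4580 lower). Of these, 2534 were higher and 2449 lower with both, against 1277 and 1245 for independent lists, and 1127 moved in opposite directions, against 2522. Part of the excess may come from the shared controls. The covariance was 0.149 (r = 0.505, same sign 67.6%), and 0.0382 (r = 0.520, 67.0%) simulated without an effect, with 1 gene shared. SCG2 (-2.02 and 0.79) and MDK (0.72 and -1.78) went in opposite directions. Between the shRNAs edgeR called 8752 genes (4159 higher and 4593 lower with shKDM5A-2). Of simulated 1.5-, 2- and 4-fold changes, 82%, 96% and 98% were called with both reagents.

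**Figure D2:**
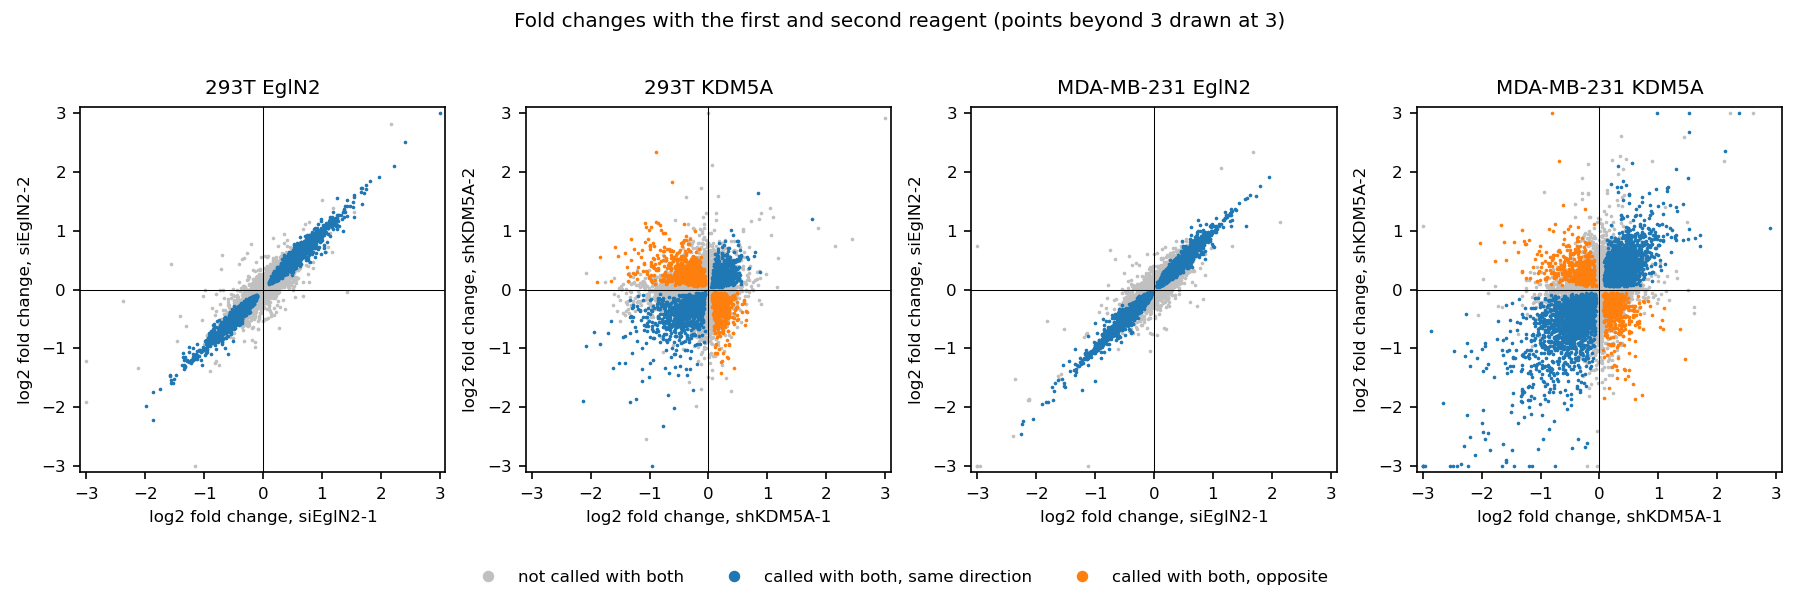
Log2 fold change with reagent 1 (horizontal) against reagent 2 (vertical) in each experiment, with 1 point per gene of average log2 CPM at or over 1, values beyond 3 drawn at 3 and colours for genes called with both reagents in the same or in opposite directions. The siRNA panels hold 0 genes with opposite calls, and the 293T shRNA panel stands for an experiment with 1493.

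**Figure D3:**
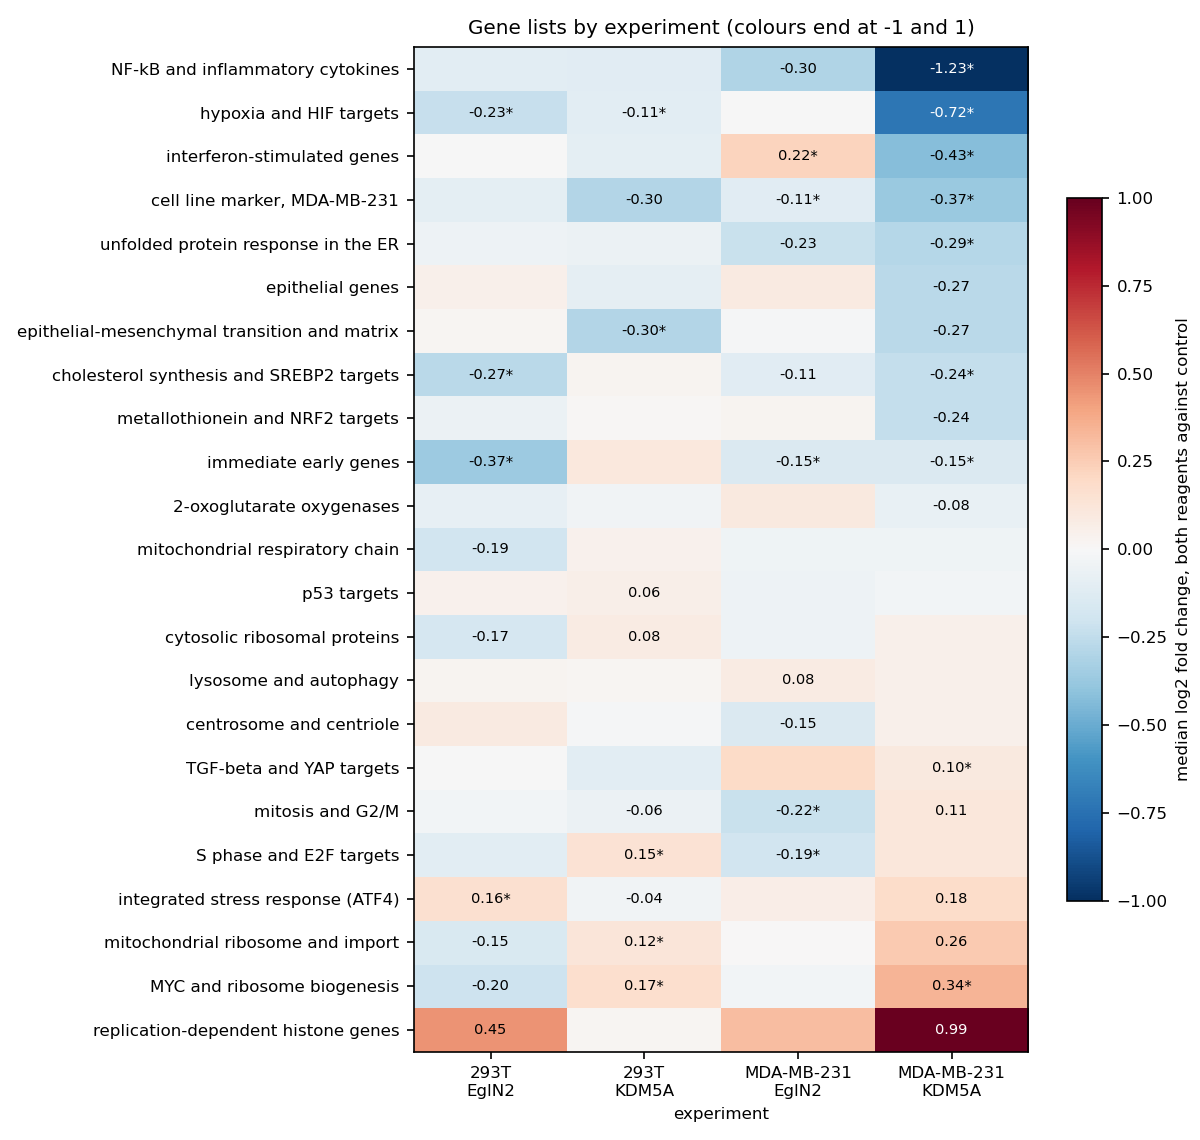
Median log2 fold change of each gene list called in at least 1 experiment, as colour from -1 (blue) to 1 (red), with the value printed where camera called the list and a star where the call held with an estimated correlation. NF-kB and inflammatory cytokines have -1.23 in MDA-MB-231 KDM5A, and hypoxia and HIF targets -0.72.

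Over the 4 experiments, camera called 46 of 128 list tests, 15 up and 31 down, and 23 of these held with an estimated correlation. The median, the mean and the test of a list had the same sign in all 46, and differed in 24 of the 82 others.

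Genes changed after each of the 2 knockdowns were compared within a line. In 293T overlaps were larger in opposite directions, but the set test below leaves chance open. Genes higher with both KDM5A shRNAs were lower with both EglN2 siRNAs in 450 cases, against 205 for independent lists. The odds ratio was 3.22 (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 1.28e-68). The reverse, lower then higher, held for 249 genes against 157 (odds ratio 1.85, adjusted p = 1.88e-14, Fisher). Higher in both were 146 against 189 (odds ratio 0.726, adjusted p = 3.52e-04, Fisher), and lower in both 178 against 170 (odds ratio 1.06, adjusted p = 0.489, Fisher). In MDA-MB-231 all 4 odds ratios were above 1, in opposite directions too, so they do not by themselves show a shared response. They were 1.76 for higher in both (664 genes against 465, adjusted p = 7.20e-27, Fisher) and 1.74 for lower in both (698 against 497, adjusted p = 1.81e-26, Fisher). Higher after KDM5A and lower after EglN2 knockdown had 1.42 (645 against 518, adjusted p = 1.86e-11, Fisher), and the reverse 1.12 (481 against 447, adjusted p = 0.0551, Fisher). Genes are not independent and expression level was not allowed for, so these p-values understate the uncertainty.

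Genes called in 1 direction with all 4 reagents of a line numbered 324 in 293T and 1362 in MDA-MB-231. The 293T set included CCNE2 and E2F1, both higher, and ACSL4, an acyl-CoA synthetase gene of lipid metabolism, which fell from 108 ± 13.3 to 47.4 ± 1.21 and 47.00 ± 0.759 CPM after EglN2 siRNA and from 85.5 ± 3.46 to 50.1 ± 2.35 and 49.5 ± 2.81 CPM after KDM5A shRNA. In MDA-MB-231 it included CSF2, CSF3 and ASB2, lower, with ASB2 at -1.56 and -1.53 and -1.86 and -2.73, and CYP24A1, higher, with 0.89 and 0.91 and 0.84 and 1.63. Across genes the mean log2 fold changes of the 2 knockdowns had r = -0.124 (rho = -0.161) in 293T and r = 0.0534 (rho = 0.0402) in MDA-MB-231. As a set, the 1272 genes higher after KDM5A shRNA in 293T were lower after EglN2 siRNA, with a median of -0.11 against 0.02 for other genes (camera adjusted p = 3.14e-04, adjusted p = 0.180 with an estimated correlation), and the 15 of them changed 1.5-fold tended up (0.443). Camera did not call the 1056 lower genes as a set in 293T (0.190), nor the 2509 higher (0.614) and 2409 lower (0.190) ones in MDA-MB-231. There the 201 higher genes changed 1.5-fold rose (0.00244), and the lower set passed downward with an estimated correlation (0.0386). The reverse, EglN2-responsive genes after KDM5A shRNA, was not among the planned tests. In 293T the 2532 genes higher after EglN2 siRNA were lower after KDM5A shRNA (median -0.05, camera adjusted p = 0.0333, 0.0386 with an estimated correlation). The 2738 lower genes were higher (median 0.04, camera adjusted p = 0.00927, 0.0756 with an estimated correlation). Of the 1.5-fold sets, 680 higher genes again went down (0.0166) and 348 lower ones did not pass (0.443). In MDA-MB-231 the 2762 higher (0.255) and 3072 lower (0.1499) genes did not pass, and passed upward and downward with an estimated correlation (both 0.0386). The 334 genes lower by 1.5-fold were lower after KDM5A shRNA too (median -0.11, camera adjusted p = 1.61e-04, 0.0223 with an estimated correlation), and 378 higher ones did not pass (0.443). These sets were chosen on these samples, so their direction after the knockdown that defined them is no independent evidence.

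The same knockdown was then compared between lines. After EglN2 siRNA, 953 genes were higher and 1320 lower with all 4 reagents, against 403 and 541 for independent lists, with an odds ratio of 4.86 for higher genes (adjusted p = 1.71e-200, Fisher) and 6.37 for lower ones. FYN, a tyrosine kinase gene, fell with log2 fold changes of -1.23 and -1.24 in 293T and -1.34 and -1.37 in MDA-MB-231, and EIF4H, ORMDL3 and PSKH1 were in this set. After KDM5A shRNA, 507 genes were higher and 333 lower with both shRNAs in both lines, against 214 and 146 (odds ratios 3.93 and 3.34, adjusted p = 1.05e-94 and 9.31e-55, Fisher). IGF2 fell from 35.6 ± 2.29 to 11.8 ± 0.801 and 4.75 ± 0.289 CPM in MDA-MB-231 as it did in 293T, GADD45B rose from 16.8 ± 1.86 to 33.3 ± 0.892 and 28.1 ± 0.730 CPM, and DDX28 rose with 0.64 and 0.43. Across genes the lines had r = 0.344 (rho = 0.403) after EglN2 siRNA and r = 0.164 (rho = 0.267) after KDM5A shRNA. A test of the difference, MDA-MB-231 minus 293T, called 4543 of 14579 genes for EglN2 (2510 more positive in MDA-MB-231, 2033 more negative) and 6601 of 14767 for KDM5A (3358 and 3243). In simulated data this test called 86% and 78% of genes whose effect differed 1.5-fold.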

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

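Chosen only after the result was seen were the tests of an EglN2 siRNA in the unnumbered control, of effects that belong to each shRNA and of a deeper knockdown with 1 shRNA; the other tests in this part were set out first.

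The edgeR test of the difference between lines flagged these results. For EglN2 it called 4543 of 14579 genes and 128 of 215 named genes, 36 with opposite signs. The difference in log2 fold change, MDA-MB-231 minus 293T, was -0.70 for EGLN2, 0.41 for EGLN1, 0.81 for EGLN3 and -0.37 for KDM5A. The KDM5A value rests partly on the unnumbered 293T control (40.0 CPM, other controls 56.6 and 57.0). For KDM5A the test called 6601 of 14767 genes, and 193 of 240 named genes differed, 88 with opposite signs. The difference was -0.31 for KDM5A, -0.22 for EGLN1, -0.21 for EGLN2, -1.06 for EGLN3, -0.22 for KDM5B and -0.12 for KDM5C.

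Lists differed too, by limma's camera on the same difference, where a median above 0 means a more positive effect in MDA-MB-231. After EglN2 siRNA, 15 of 30 lists differed, and 5 of these calls held with an estimated correlation. By limma's camera, more positive in MDA-MB-231 and held were hypoxia targets (median 0.27, adjusted p = 3.53e-06), cholesterol synthesis (0.17, adjusted p = 7.87e-05) and immediate early genes (0.34, adjusted p = 0.00116). More negative by limma's camera and held were mitosis (-0.17, adjusted p = 3.49e-09) and ATF4 targets (-0.14, adjusted p = 3.62e-07). The other calls were lost with an estimated correlation. They were oxygenases (0.0126), FOXO targets (0.0313), ribosomal proteins (0.0313), the respiratory chain (0.0146), mitochondrial ribosome (2.63e-04) and MYC and ribosome biogenesis (6.65e-05), all more positive. More negative were centrosome (4.36e-06), neuronal genes (0.0377), S phase (2.58e-04) and the unfolded protein response (0.00124).

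After KDM5A shRNA, 14 of 31 lists differed and 11 held. More negative in MDA-MB-231 by limma's camera were hypoxia targets (median -0.61, adjusted p = 4.61e-45), NF-kB genes (-0.72, adjusted p = 3.49e-09) and cholesterol synthesis (-0.29, adjusted p = 2.29e-08). So were the unfolded protein response (7.71e-08), NRF2 targets (0.00208), 293T markers (0.00313) and immediate early genes (0.00537). More positive by limma's camera were histone genes (0.94, adjusted p = 3.14e-04), MYC and ribosome biogenesis (1.43e-08), mitosis (2.96e-06) and ATF4 targets (6.71e-06). All 14 differences use the mean of both shRNAs, which alone went in opposite directions in 293T for ATF4 targets, histone, cholesterol and immediate early genes, the unfolded protein response and 293T markers, and in MDA-MB-231 for cholesterol and mitosis. Lost with an estimated correlation were the respiratory chain (0.00313), mitochondrial ribosome (1.73e-04) and MDA-MB-231 markers (0.0377).

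Other splits of the libraries were counted beside these results. For the difference between lines, only the real of 60 drawn splits gave as many genes (EglN2 4543, highest other 2332, KDM5A 6601 and 2768). The same held for calls with both reagents in 293T EglN2 (5306 and 0), MDA-MB-231 EglN2 (5848 and 1) and MDA-MB-231 KDM5A (4983 and 2711). Other splits mostly mix knockdown and control libraries, so they test neither a difference between lines nor agreement of reagents. Chance cannot be excluded for 293T KDM5A, where 4 of 60 splits gave as many as 2336 and the highest other 4226. The largest of these splits, with 4226, 2853 and 2841 genes, put a whole shRNA group in the place of the controls. This points to a difference between the shRNA groups. For genes called with all 4 reagents, 324 in 293T, 1362 in MDA-MB-231, 2273 for EglN2 and 840 for KDM5A, the highest other was 0. Other splits called almost no genes to share, so they do not test whether an overlap exceeds that of independent lists. In 293T it did not in total, with 146 higher and 178 lower against 189 and 170. With the real groups 46 lists were called, and with another split up to 39. Wrongly drawn groups can thus give nearly as many list calls, so chance is not excluded for single lists. For genes responsive to KDM5A, the lowest unadjusted p in the 293T EglN2 experiment was 3.93e-05, but 18 splits reached it and the lowest other was 2.69e-07, so chance cannot be excluded. In MDA-MB-231 it was 0.134 and the lowest other 0.158, but 0.134 does not pass, so there is no call for the splits to test. Within single comparisons the splits, 10 each, are too few for a share under 0.05. Highest others were 0 against 6190 and 2 against 6019 in 293T EglN2, 1 against 7340 and 1 against 6777 in 293T KDM5A, 0 against 6725 and 0 against 6859 in MDA-MB-231 EglN2, and 0 against 8548 and 1 against 9120 in MDA-MB-231 KDM5A. Between reagents they were 0 against 0 (10 splits as large) and 5 against 1 (7 splits as large) for EglN2, and 0 against 8569 and 0 against 8752 for KDM5A.

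The unnumbered 293T control stood apart from the other siRNA controls. A smooth trend with transcript length and GC content took away 16.0% of the variance of its deviation, which argues against such a trend as the whole cause. RNA of MDA-MB-231 cells would bring their markers, but AXL, CD274 and NT5E rose by a median of 0.0465% of their MDA-MB-231 level, which argues against it. In CPM without TMM scaling, EGLN2 was 3.06 times as high as in the highest siRNA library (70.2 against 23.0), which argues against a library of cells given an EglN2 siRNA. A culture or library made apart from the others stays open, and no biological explanation was tested.

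Both EglN2 siRNA groups were nearly indistinguishable, with 0 and 1 genes called between them. The median 95% half-width of the difference was at most 1.11-fold, which argues against too large a spread. Libraries of different siRNA groups differed at most 1.15 times as much as libraries of the same group, against 9.38 and 18.3 times for the shRNAs, so cells given the same siRNA, or siRNAs with the same seed, are a candidate explanation. A like response to the loss of EglN2 after 2 different siRNAs cannot be told apart from this. All 4 comparisons (4 of 4) were led by the same 7-base match, GACAGAA, which was set out as evidence against it, but a cellular regulator that answers to EglN2 and acts through this match would give the same value, and the siRNA sequences are not given.

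The KDM5A shRNAs moved 1493 genes in 293T and 1127 in MDA-MB-231 in opposite directions. Effects that belong to each shRNA would recur in both lines, and the difference between the shRNAs correlated across genes between lines (Spearman's rho 0.346), which is consistent with them. A deeper knockdown with 1 shRNA would scale changes without turning them, but up to 39.0% of genes called with both were opposite (18.5% in MDA-MB-231), which argues against it as the whole cause. With a trend in transcript length and GC content taken away, at least 65.1% of opposite calls were kept, and since the trend is confounded with the shRNA groups this cannot be told apart.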

How the results depend on the processing

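The settings chosen after seeing the data were the control libraries that stood apart left out and the genes with the leading 3' UTR match left out; the tests under all other settings were planned. Every log2 fold change of a targeted gene kept its direction and call under all settings run. With the replicate block, genes called with both reagents numbered 6266, 2222, 5805 and 4932 in 293T EglN2, 293T KDM5A, MDA-MB-231 EglN2 and MDA-MB-231 KDM5A, against 5306, 2336, 5848 and 4983, and the called lists 43. The counts between the EglN2 siRNAs were then 11 in 293T and 2 in MDA-MB-231.

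An adjusted p under 0.01 calls fewer genes by construction. In 293T EglN2 it left 3741 and 3507 genes, 3175 with both siRNAs. It left 1548 with both shRNAs in 293T, 148 with all 4 reagents of 293T, 1431 and 549 with all 4 of EglN2 and KDM5A, 2818 for the EglN2 difference between lines, and 0 between the siRNAs in MDA-MB-231. A 1.5-fold minimum left, for reagent 1, reagent 2 and both, 1383, 1344 and 1064 in 293T EglN2, 1083, 854 and 134 in 293T KDM5A, 951, 972 and 726 in MDA-MB-231 EglN2, and 1866, 2476 and 763 in MDA-MB-231 KDM5A. Between the shRNAs it left 1793 and 2243, in all 4 comparisons of a set 9 in 293T, 61 in MDA-MB-231, 204 for EglN2 and 10 for KDM5A, and for the differences between lines 777 and 1257. DESeq2 gave 1522 with both shRNAs in 293T, 199 with all 4 reagents of 293T, 548 with all 4 of KDM5A and 1 between the siRNAs of 293T; the cause was not tested. The 6 libraries alone gave 2 and 5 between the siRNAs in 293T and MDA-MB-231. In MDA-MB-231 no low-count filter gave 0 there and an average log2 CPM of at least 1 gave 3; the cause was not tested. Without the doubted controls these counts were 4 and 0. Leaving out carriers of the 3' UTR match, which tests fewer genes, gave 193 with all 4 reagents of 293T.

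Leaving out each library in turn gave 0 to 4 genes between the siRNAs in 293T and 0 to 7 in MDA-MB-231. Genes called with both reagents ranged from 4043 to 6760, 1892 to 2161, 5365 to 5562 and 4423 to 4992 in the order above. For all 4 reagents they ranged from 254 to 472 in 293T, 1245 to 1384 in MDA-MB-231, 1867 to 2837 for EglN2 and 708 to 831 for KDM5A. The differences between lines ranged from 3808 to 5394 and 5943 to 6639, and the called lists from 43 to 50.

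Lists called numbered 23 with an estimated correlation and 101 with fry, which asks another question, against 46. With reagent 1 alone the direction turned for ATF4 (7.06e-06) and p53 targets (0.146) in 293T KDM5A and for cholesterol (0.806) and epithelial genes (0.992) in MDA-MB-231 KDM5A, and with reagent 2 alone for mitosis there (0.964). Among lists not called on the mean, each shRNA alone called neuronal and histone genes in 293T KDM5A and ribosomal proteins in MDA-MB-231 KDM5A in opposite directions. The cause was not tested. The genes higher after KDM5A shRNA had 0.180 in 293T EglN2 with an estimated correlation and turned with 1.5-fold sets (0.443), against 2.45e-05 to 6.81e-04 with a library left out. In MDA-MB-231 the 1.5-fold higher set passed (0.00244), as did the lower set with an estimated correlation (0.0386); the cause was not tested.

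Named genes turned in no setting run. Of 10944 calls with a library left out, 361 were lost and 8 gained, and DESeq2 lost 58 of 1195. Median-of-ratios size factors and scaling moved the median of all genes by less than 0.1. Settings for values other than counts do not apply. Depth limits mainly genes with few counts, and at most 68% of 1.5-fold changes were called with both reagents in 3 of the simulated experiments.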

Other observations

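The tests of genes shared by all 8 reagents, of the carriers of 3' UTR matches and without controls or carriers were chosen only after the values were seen, while the search for a leading match was set out first. With all 8 reagents, 44 genes were higher and 38 lower of 13702 tested in every experiment, where 4 independent experiments would share 6.41 and 5.83. Lists of the same target already agreed between lines, which may account for most of this excess. Higher in all 8 groups were the cell cycle genes CCNE2, E2F1 and RRM2, the apoptosis gene BCL2L11, KEAP1, a repressor of NRF2, and FMR1. RRM2, a subunit of ribonucleotide reductase, had log2 fold changes of 0.97 and 0.98 in 293T EglN2, 0.28 and 0.19 in 293T KDM5A, 0.50 and 0.50 in MDA-MB-231 EglN2 and 0.63 and 0.32 in MDA-MB-231 KDM5A. FMR1 had 0.38 and 0.39, 0.36 and 0.24, 0.24 and 0.28 and 0.33 and 0.33. Lower with all 8 were NDRG1, P4HA2 and PFKFB3, which hypoxia induces, the ubiquitin ligase gene VHL, the structural genes VIM, LMNA and CAV1, and ACSL4. VHL had -0.21 and -0.26, -0.22 and -0.23, -0.36 and -0.33 and -0.52 and -0.26.

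Genes that fell after EglN2 siRNA often carried GACAGAA in their longest 3' UTR. In 293T 15.4% of 13365 genes with a 3' UTR carried it, 21.7% of those lower with both siRNAs and 12.4% of those higher. Of 300 genes lower by at least 1.5-fold, 129 (43.0%) carried it. In MDA-MB-231 the shares were 15.3%, 23.9% and 9.75%, and 148 of 296 genes lower by 1.5-fold carried it. The match was selected on these same fold changes, so these shares restate the selection and are no separate test, and they make no allowance for the length of the 3' UTR. The match led 15955 tested in 293T and 15857 in MDA-MB-231 with both siRNAs, with scores of -17.2, -17.6, -20.4 and -20.5, where the lowest of 100 shuffles had -4.90, -4.87, -5.12 and -4.82. The search itself did allow for length and GC content. The same 7 bases occur in 11 of 18 EGLN2 transcripts, in 0 of them in the 3' UTR.

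After KDM5A shRNA the leading matches differed between shRNAs. AGGGACA led with shKDM5A-1 in both lines (scores -16.6 and -11.6), AAGCCTT with shKDM5A-2 in 293T (-18.8) and GCCTTAC with shKDM5A-2 in MDA-MB-231 (-13.5). These last matches overlap, with AGCCTTA, which lies across both, ranked 2 in both lines. In 293T 26.9% of genes with a 3' UTR carried 1 of the leading matches, 43.4% of those lower with both shRNAs, 14.3% of those higher and 38.7% of 93 lower by 1.5-fold. In MDA-MB-231 the contrast was weaker, with 19.2%, 21.4%, 15.9% and 25.5% of 423. These matches too were selected on the same fold changes. KDM5A transcripts held these matches in 3, 2 and 2 of 11 for AAGCCTT, AGGGACA and GCCTTAC.

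Pairing of a seed in a siRNA or shRNA with 3' UTRs is a candidate explanation for part of these falls, with 4 of 4 EglN2 comparisons led by the same match. A cellular regulator acting through these matches is another. Without carriers, the correlation between lines across genes was 0.401 in place of 0.433 for EglN2 (9883 and 11689 genes) and 0.168 in place of 0.213 for KDM5A. Genes called with both reagents without carriers numbered 4472 in 293T EglN2, 1738 in 293T KDM5A, 4891 in MDA-MB-231 EglN2 and 4126 in MDA-MB-231 KDM5A. Genes without an annotated 3' UTR count as having no match here. Effects that follow from genes lowered in this way, or sites outside the longest 3' UTR, were not tested.

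Replicate pairs other than those with a control that stood apart had a chi-square per degree of freedom of 1.33 to 3.101. Without these controls 6760 genes were called with both siRNAs in 293T and 5395 in MDA-MB-231.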
